A study of Homo sapiens with 6 samples.

How the data were processed

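Gene expression was compared on 6 arrays of the human colon fibroblast line CCD-18Co. The labels number 3 control and 3 extract samples as biological replicates, without saying whether these came from separate passages or days, so p-values measure only the spread between these samples. Cells at passage 13 to 14 were used on day 5 after seeding, at about 90% confluence, per the labels' protocols. The extract cultures received a bitter orange extract that had been digested in the test tube, at about 60 µM total flavanones in the medium, for 24 h, and the control cultures received matching amounts of the digestive enzymes and salts for the same time. Biotin-labelled cRNA was made from 5 µg of total RNA.

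The values deposited by the authors are probe set intensities on a linear scale, with 1 value per probe set and array. The submitters' processing notes name RMA and GCOS without a version or a role, and the background correction and any step back from a log scale are not given in the sources used here. The array quartiles lay close together, with lower quartiles of 10.68 to 11.15, medians of 22.97 to 23.98 and upper quartiles of 95.31 to 101.3, and no value lay below 1, so no floor was needed. The values were turned to log2 and not normalized again. Arrays carry no read depth, and the small number of arrays limits the precision. No detection calls or scan dates were used here, so a batch that follows the groups could not be examined.

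Of 54675 probe sets, 62 control probe sets were left out. Among the remaining 54613, the platform annotation gave exactly 1 gene symbol for 41091, several for 1801 and none for 11721. Probe sets with several genes or none were not used for gene results. Symbols were updated through the gene identifier to the GRCh38.p14 gene table, used for names only, and 54 probe sets kept the symbol of the annotation. Each of the 19775 genes was represented by its probe set of highest mean over the 6 arrays, a choice that matters for the 10523 genes with several probe sets. Some members of the fixed lists, and 1 gene fixed for naming, are not reported here.

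The comparison of extract with control used limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values, no covariate, and Benjamini-Hochberg adjustment over all genes. There were 4 residual and 4.7 prior degrees of freedom. A gene was called at adjusted p under 0.05, and a second count also asked for a fold of at least 1.5. Errors of log2 changes are moderated standard errors, errors of intensities are SD over n = 3 arrays, and intervals are 95% intervals. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over 44 lists, of which 37 were pathway lists and 7 were cell type marker lists. The same lists were tested with an estimated correlation and with fry. The smallest list size allowed was 5 measured members. RNA quality measures were compared by exact two-sided permutation tests.

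The groups, tests, gene lists, the alternatives except 1 and the rule for named genes were set before the data were examined. The rule names the 12 largest rises and the 12 largest falls among called genes whose extract arrays all lay on one side of the control arrays. It adds up to 4 members of each described list with the smallest p, and CYP1A1, CYP1B1, NQO1, HMOX1, PTGS2, CDKN1A, CCND1, COL1A1 and ACTA2 whatever their result. Genes named outside the rule are said to have been chosen after their values were seen.

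The tests were tried on simulated data with the means of these 19775 genes, variances drawn from the fitted prior and no correlation between genes. Over 20 simulations with 200 changed genes each, the fit recovered 26.2% of genes changed 1.3 fold, 79.9% at 1.5 fold, 98.3% at 2 fold and 99.8% at 3 fold, and 4.79% of its calls were false. A list shifted by 0.3 on the log2 scale was found in 20 of 20 simulations, with 1 call among the other lists. Smaller shifts, such as the median of -0.10 of the proteasome list, and correlated genes were not simulated. Alternatives were the replicate number as a block, each array left out, a filter on dim genes, quantile normalization again, median centring, a trended and robust prior, array weights, the mean of a gene's probe sets, no _x_at or _s_at probe sets, every probe set tested singly, and other thresholds. The alternative added after seeing the data left out replicate 3 of both groups. Figures were drawn with matplotlib 3.10.9.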

Results

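Gene expression was measured on Affymetrix arrays in CCD-18Co cells, a fibroblast line from normal human colon kept by a public cell bank. There were 3 control arrays, from cultures given digestive enzymes and salts, and 3 extract arrays, from cultures given a digested bitter orange extract with about 60 µM flavanones, the polyphenols typical of citrus fruit, for 24 h. The question of the comparison is which genes differ in fibroblasts exposed to the digested extract.

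PDK4, the kinase that blocks pyruvate dehydrogenase and so spares glucose, had the largest rise, from an intensity of 25.49 ± 3.01 (SD, n = 3) in control to 306.3 ± 74.6 (SD, n = 3) with extract. SST, which encodes the peptide hormone somatostatin, rose to 98.38 ± 14.1 (SD, n = 3) from 14.14 ± 3.63, a control level below every array's median. The control level of PDK4 lies next to the array medians of 22.97 to 23.98, and neither level was shown to lie above background, so both folds are uncertain. The angiotensinogen gene AGT rose 2.96-fold. Of 32 NF-kB cytokine and chemokine genes 20 rose, and of 29 interferon-stimulated genes 20 rose, the latter list with camera adjusted p = 0.33 at an estimated correlation. The urea transporter gene SLC14A1 had the largest fall, with a log2 change of -1.67. In all, 620 of 19775 genes (3.14%) changed at a limma adjusted p under 0.05, 416 of them higher and 204 lower with extract.

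Among the largest rises, the limma log2 change was 3.57 ± 0.16 (SE) for PDK4, with adjusted p = 3.71e-05, and 2.82 ± 0.18 for SST, with adjusted p = 0.00026. AGT rose by 1.56 ± 0.08 and TCEAL7 by 1.37 ± 0.08. TSPAN2, a tetraspanin gene, rose by 1.27 ± 0.10, and GABRA2, a subunit of the GABA-A receptor, by 1.25 ± 0.14. NR4A2, an orphan nuclear receptor of the immediate early class, rose by 1.25 ± 0.10, and its 2 further probe sets were also higher. All its probe sets are of the _x_at or _s_at type, so it could not be tested without them. Of the 2 further PDK4 probe sets, 1 rose by 1.32 ± 0.11, and the other, which was dim, was at -0.16 with no call. C11orf96 rose by 1.77 ± 0.07 and RGCC, a regulator of the cell cycle, by 1.62 ± 0.12, but each rests on a single bright probe set of the _s_at type. Without that type the dim remaining probe sets gave -0.0421 for C11orf96 and -0.00789 for RGCC, with no call. CXCL5, TNFAIP6 and CXCL3 complete the 12 largest rises and are described with their list.

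Among the falls, SLC14A1 decreased from 256.8 ± 8.07 to 80.88 ± 4.12 (SD, n = 3), and its further probe set changed by -1.70. The prostatic acid phosphatase gene ACP3 fell by 1.20 ± 0.12 on its _s_at probe set, against -0.38 and no call without that type, and MAP3K7CL fell by 1.15 ± 0.11. MAP3K7CL has only an _s_at probe set here, so it could not be tested without that type. CHRM3, the muscarinic M3 receptor, fell by 1.06 ± 0.08, and all 5 further probe sets were lower. The guidance genes SEMA7A and RGMB fell by 1.02 ± 0.07 and by 1.01 ± 0.07. E2F7, an E2F family repressor, fell by 0.95 ± 0.12, and HBEGF, an EGF receptor ligand, fell by 0.82 ± 0.10. The dimmer further probe set of E2F7 was at -0.26 with no call. NAV3, ARHGAP18 and LRRC17 had log2 changes of -0.81, -0.80 and -0.76. HMGA2, a chromatin protein gene linked to growth, fell by 0.78 ± 0.07 on its bright _s_at probe set, while the dim set used without that type gave 0.04 and no call. CCND1, which encodes cyclin D1, fell by 0.70 ± 0.10, with limma adjusted p = 0.00947. Its further probe set, tested singly, was at -0.37 with no call.

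**Figure D1:**
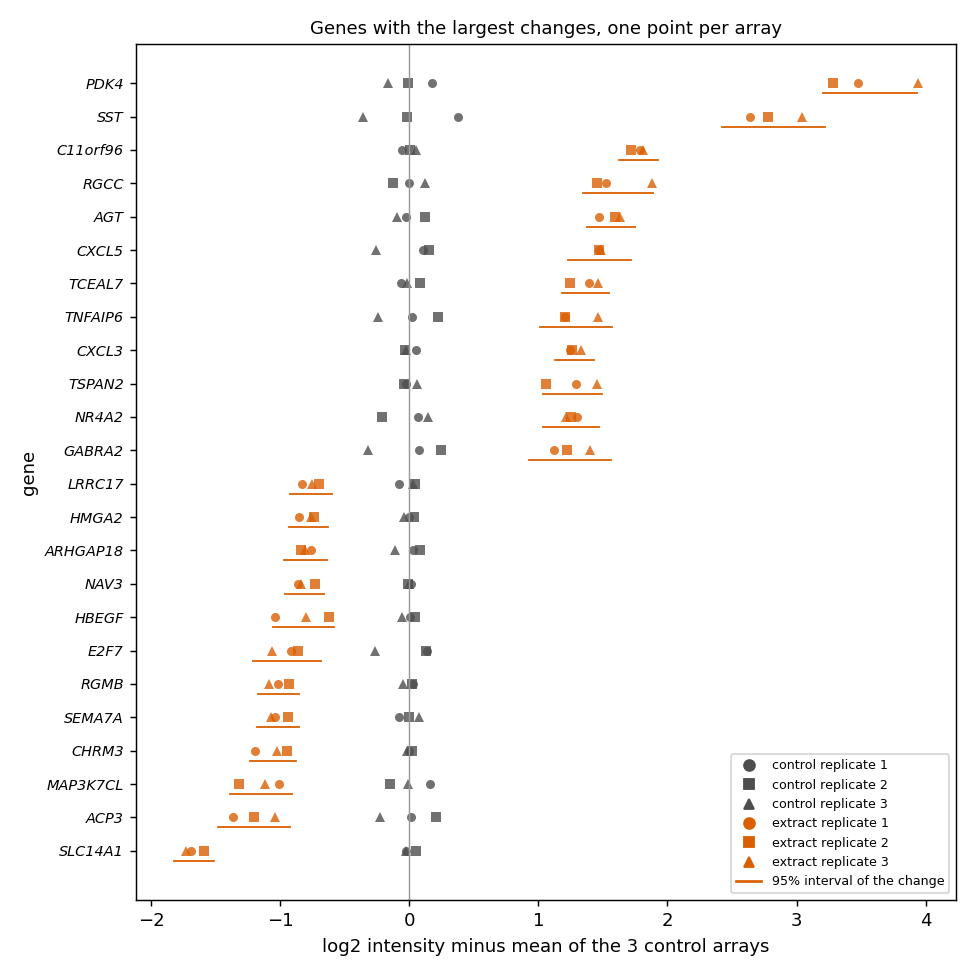
Log2 intensity of the 12 largest rises and 12 largest falls on each of the 6 arrays, relative to the mean of the 3 control arrays, with lines for the 95% interval of the change. Mean differences run from 3.57 for PDK4 to -1.67 for SLC14A1. The extract arrays lie clear of the control arrays for every gene shown because the genes were chosen that way.

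Of 32 measured NF-kB cytokines and chemokines, genes driven by inflammatory signalling, 20 rose, 2 fell and 10 did not pass (23 rose and 2 fell when adjusted over the list alone). The neutrophil chemokine genes CXCL5, CXCL3 and CXCL6 rose by 1.47 ± 0.11, 1.28 ± 0.07 and 0.99 ± 0.07 (log2 ± SE, limma), with adjusted p = 0.000583, 7.7e-05 and 0.000549. CXCL5 rests on an _x_at probe set, and its further _s_at set rose by 1.66, while the dim set used without these types rose by 0.55. TNFAIP6, a hyaluronan-binding protein gene, rose by 1.29 ± 0.12 and TNFAIP3, a brake on NF-kB signalling, by 0.92 ± 0.07. Both genes have only _s_at probe sets, so neither could be tested without that type. IL6 at 0.67 and IL1B at 0.65, chosen after their values were seen, rose as well. The members that fell were ICAM1 at -0.40 and CSF1 at -0.43, also chosen after their values were seen. The call of ICAM1 was lost with 4 single arrays left out (control replicate 1, control replicate 3, extract replicate 1 or extract replicate 2), and that of CSF1 with those or extract replicate 3, with adjusted p up to 0.0721 and 0.0912. The members that rose numbered 13 without extract replicate 1. As a list these genes shifted higher in camera with adjusted p = 6.36e-20, and this was the only list still called with an estimated correlation, at adjusted p = 0.018.

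Of 29 interferon-stimulated genes, the antiviral genes induced by interferons, 20 rose, none fell and 9 did not pass (24 rose and 1 fell when adjusted over the list alone), with a median fold of 1.57. The count that rose was 13 without extract replicate 2 and 13 without extract replicate 3. CXCL10, a T cell chemokine gene, rose by 1.15 ± 0.09 (log2 ± SE, limma), and OAS2, a sensor of double-stranded RNA, by 0.95 ± 0.08. The guanylate-binding protein gene GBP1 rose by 0.75 ± 0.08, and ISG15, a ubiquitin-like modifier, by 0.68 ± 0.07. The list was called by camera with adjusted p = 3.27e-23, but had adjusted p = 0.33 with an estimated correlation. Leukocyte markers, which would come with immune cells in a culture, had a median log2 change of -0.04, and none of 17 rose or fell in limma, while 1 rose when adjusted over the list alone and 1 without control replicate 3. Of these 17, 16 were no brighter than the median gene in control.

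Of 17 genes of prostaglandin synthesis and response, PTGES, PLA2G4A and PTGS2 rose and the other 14 did not pass, as when adjusted over the list alone. PTGES, the inducible prostaglandin E synthase, rose by 1.09 ± 0.09 (log2 ± SE, limma). PTGS2, which encodes the cyclooxygenase COX-2, rose from 2986 ± 313 to 4826 ± 105 (SD, n = 3), and PLA2G4A, which releases arachidonic acid, rose by 0.72 ± 0.08. PTGES and PTGS2 are also members of the cytokine list. Camera called the list with adjusted p = 0.0461, but adjusted p was 0.427 with an estimated correlation. It was also 0.147 without control replicate 1, 0.0736 without control replicate 2, 0.102 without extract replicate 2 and 0.0837 without extract replicate 3.

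Of 15 glucocorticoid-responsive genes 8 rose and 7 did not pass (9 rose and 1 fell when adjusted over the list alone). The count that rose was 3 without control replicate 1 or 2 or extract replicate 1 or 3, and 4 without extract replicate 2. KLF9, a Kruppel-like factor, rose by 0.73 ± 0.09 (log2 ± SE, limma). Its 4 further probe sets were higher too, but when tested singly only that at 0.49 had a call, against 0.008, 0.15 and 0.08. CRISPLD2, a secreted protein gene, rose by 0.82 ± 0.09, although its dimmer further probe set was at -0.18 with no call. Camera gave this list adjusted p = 6.3e-06, and adjusted p = 0.147 with an estimated correlation. Of 29 immediate early and AP-1 genes 7 rose and 3 fell (14 and 4 adjusted over the list alone), among them FOS at 0.65 ± 0.07 and IER3 at 0.53 ± 0.07, both higher. HBEGF fell, as did SPRY4 at -0.52 and FOSL1 at -0.32, chosen after their values were seen and lost with most of the single arrays left out, with adjusted p up to 0.0662 and 0.145. The members that changed numbered 5 higher and 1 lower without control replicate 3 or extract replicate 1. The list had camera adjusted p = 5.37e-05, which was 0.427 with an estimated correlation and 0.254 without _x_at and _s_at probe sets. Of 23 hypoxia response genes 3 rose (7 rose and 1 fell adjusted over the list alone), with the vasodilator peptide gene ADM at 0.68 ± 0.06 and the lipase inhibitor gene ANGPTL4 at 0.70 ± 0.09. MXI1, at 0.47 ± 0.07, lost its call without control replicate 1 or extract replicate 2, with adjusted p up to 0.0543. Camera adjusted p was 3.06e-06 for that list and 0.427 with an estimated correlation. ANGPTL4 belongs to the glucocorticoid, hypoxia and PPAR lists alike.

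Of 21 genes of fatty acid oxidation and PPAR targets 4 rose and 1 fell (9 and 2 adjusted over the list alone). PLIN2, which coats lipid droplets, rose from 3871 ± 379 to 7173 ± 469 (SD, n = 3), and PDK4 and ANGPTL4 also belong here. FABP4, a fatty acid carrier, fell by 0.66 ± 0.08 (log2 ± SE, limma), while its dim further probe set was at 0.17 with no call. The list had camera adjusted p = 0.00385, then 0.494 with an estimated correlation and 0.0764 without _x_at and _s_at probe sets. Of 12 LXR targets, genes of the sterol-sensing nuclear receptor, 4 rose (6 rose and 1 fell adjusted over the list alone), with the cholesterol exporter gene ABCA1 at 0.47 ± 0.07. The call of ABCA1 held with each array left out but not with the mean of its probe sets, at 0.24. PLTP lost its call when any array but extract replicate 2 was left out, NR1H3 for any but control replicate 2 and SMPDL3A for each of the 6, with adjusted p reaching 0.102, 0.142 and 0.132. LXR targets had camera adjusted p = 0.00385, and 0.33 with an estimated correlation. Of 19 cholesterol synthesis genes 3 rose, INSIG1 at 0.41, LSS at 0.42 and STARD4 at 0.34, with the same count over the list alone. INSIG1 lost its call when any array but control replicate 2 was left out, LSS for any but control replicate 1 and STARD4 for each of the 6, with adjusted p up to 0.0976, 0.0886 and 0.135. Their list had camera adjusted p = 0.0107, but 0.426 with an estimated correlation and 0.0507 without control replicate 3.

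CYP1B1, a cytochrome P450 gene induced through the aryl hydrocarbon receptor, rose from 81.87 ± 3.33 to 154.9 ± 9.02 (SD, n = 3), a log2 change of 0.92 ± 0.07 (limma adjusted p = 0.000613). CYP1A1, the classical target of that receptor, was dim, at 17.24 ± 1.43 and 23.59 ± 0.968. Its rise of 0.45 ± 0.08 had limma adjusted p = 0.0191, but the call was lost without control replicate 1, control replicate 2, extract replicate 1 or extract replicate 2, with adjusted p up to 0.0833. The other 9 of 11 receptor targets did not pass (2 rose and 1 fell adjusted over the list alone), and camera did not call the list (adjusted p = 0.442), while fry, which does not compare a list with other genes, had adjusted p = 0.0286, higher. No member of 27 NRF2 antioxidant targets passed on its own (1 rose adjusted over the list alone), with HMOX1 at 0.13 ± 0.07 and NQO1 at 0.11 ± 0.07. The AKR1C1 and AKR1C2 probe sets, at 0.31 and 0.39, serve near-identical genes and may share signal. The list as a whole shifted higher with camera adjusted p = 0.00813, which was 0.445 with an estimated correlation and 0.0754 without extract replicate 3.

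Autophagy and lysosome genes shifted higher as a list with camera adjusted p = 0.000243, then 0.427 with an estimated correlation, although none of 23 passed in limma (6 rose adjusted over the list alone). WIPI1 and NPC2 were at 0.31 and 0.29. Proteasome genes shifted lower with camera adjusted p = 1.33e-05, then 0.494 with an estimated correlation, and 24 of 25 were lower, by a median of -0.10. PSMD2 was the member that passed, at -0.41, also when adjusted over the list alone, and its call was lost with 4 of the single arrays left out (control replicate 1 or 2, extract replicate 1 or 3), with adjusted p up to 0.0772. Endoplasmic reticulum chaperones shifted lower with camera adjusted p = 0.00576, then 0.507 with an estimated correlation and 0.177 without _x_at and _s_at probe sets. None of 19 passed, also when adjusted over the list alone, and CRELD2 and DNAJB11 had values of -0.24 and -0.23.

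Contractile genes of myofibroblasts shifted lower with camera adjusted p = 0.00133, and 0.494 with an estimated correlation, and 1 of 21 fell (2 adjusted over the list alone). SMTN, which encodes the actin-binding smoothelin, fell by 0.51 ± 0.07 (log2 ± SE, limma), and ACTA2, the smooth muscle actin that marks myofibroblasts, was at -0.08 ± 0.07. Smooth muscle and pericyte markers, which share 5 measured genes with that list, shifted lower with camera adjusted p = 0.0445, and 0.638 with an estimated correlation. SYNPO2 was the 1 of 13 that fell, by 0.63 ± 0.07 (3 fell adjusted over the list alone), and its mean over probe sets, at -0.38, had no call. Among its 6 further probe sets, those at -1.09 and -0.78 passed when tested singly, and the rest had no call. The marker list lost its call without control replicate 1 (0.0555), control replicate 3 (0.298), extract replicate 2 (0.0753) or extract replicate 3 (0.0561). Camera did not call the other marker lists. KRT18 fell among 20 epithelial markers and FABP4 among 10 adipocyte markers. PDPN rose among 14 fibroblast markers, chosen like KRT18 after its value was seen, but lost its call for each of the 6 arrays left out, with adjusted p up to 0.137. None of 14 endothelial or 11 glial and neuronal markers passed.

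Camera called neither matrix list. Of 40 collagens and fibre-forming matrix genes 5 rose and 3 fell (6 and 5 adjusted over the list alone), with camera adjusted p = 0.744 and a median and mean of opposite sign, at -0.07 and 0.02. The 3 that fell were TNC, LOXL1 and COL15A1, chosen after their values were seen, and each lost its call with at least 2 arrays left out in turn (extract replicate 1 or 2 for TNC), with adjusted p up to 0.0589, 0.0752 and 0.164. Without extract replicate 1 or 2, 4 rose and 0 fell, and without extract replicate 3, 4 rose and 1 fell. COL8A1 and the basement membrane gene COL4A1 rose by 0.83 ± 0.08 and 0.69 ± 0.09 (log2 ± SE, limma), and THBS2 by 0.72 ± 0.09, but with the mean of its probe sets COL8A1 was at 0.35 with no call. COL1A1, the main fibrillar collagen gene, was at -0.13 ± 0.08 on its brightest probe set, while 2 of its 4 further probe sets fell by 0.54 and by 0.51 when probe sets were tested singly. Of 25 matrix proteases and inhibitors 5 rose and none fell (7 and 3 adjusted over the list alone), with the metalloelastase gene MMP12 at 1.07 ± 0.09 and the protease inhibitor gene SERPINE2 at 0.76 ± 0.07. MMP12 had a control intensity of 27.84 ± 1.87 (SD, n = 3), near the array medians, and no further probe set, so its fold is uncertain. The count that rose was 3 without extract replicate 1, 2 or 3. For that list camera adjusted p was 0.117, while fry had adjusted p = 0.0185, higher. CDKN1A, the p21 cell cycle inhibitor, was at -0.01 ± 0.06.

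**Figure D2:**
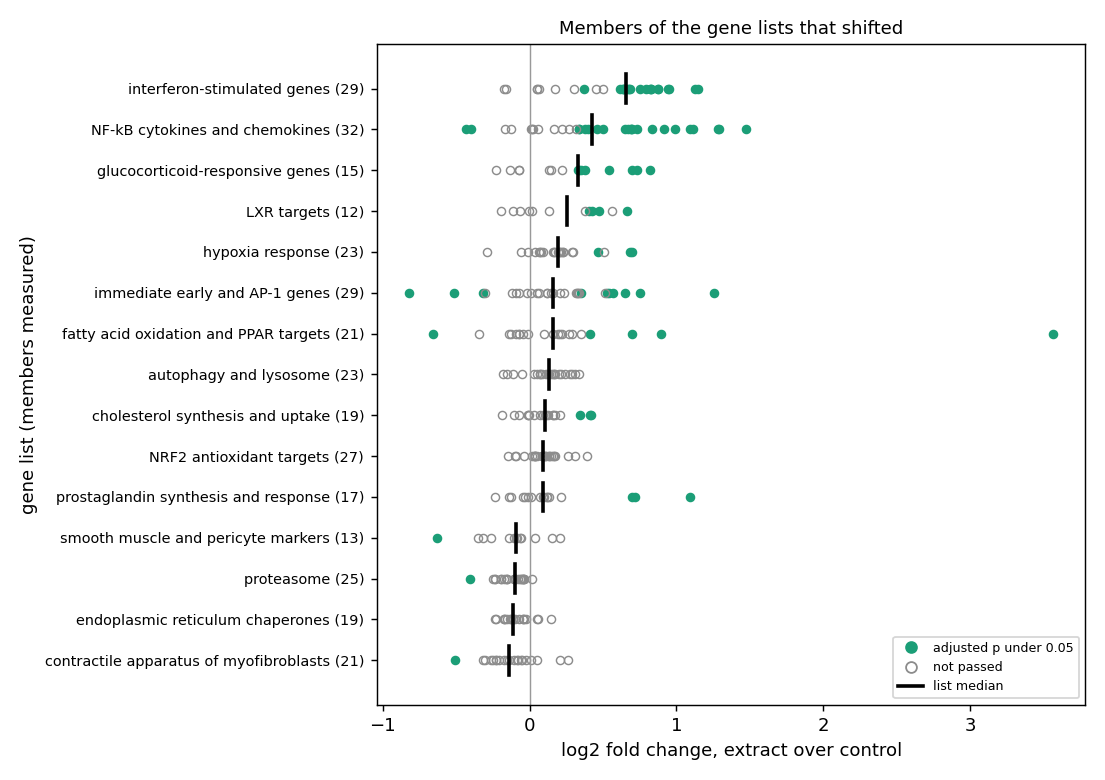
Log2 change, extract over control, of each measured member of the 15 lists called by camera, with filled points for members at limma adjusted p under 0.05 and bars for list medians. Medians run from 0.66 for interferon-stimulated genes to -0.14 for the contractile list, and only the NF-kB list kept its call with an estimated correlation.

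Of the changed genes, 193 differed at least 1.5-fold, 158 higher and 35 lower, and 4430 genes (22.4%) had separated groups where chance gives 10%. Arrays correlated at 0.9969 to 0.9979 within groups and 0.9942 to 0.9965 between groups across genes, which are not independent replicates. The 3' to 5' log2 ratio was 0.131 ± 0.025 in control and 0.126 ± 0.025 with extract for GAPDH (SD, n = 3, exact permutation p = 0.8), and 0.649 ± 0.03 and 0.599 ± 0.024 for ACTB (exact permutation p = 0.1, the smallest possible). The count of 620 genes was 308, 351 or 340 without control replicate 1, 2 or 3 and 275, 305 or 288 without extract replicate 1, 2 or 3, and it was 126 without replicate 3 of both groups, an alternative added after seeing the data. Of 78 named genes with a call, 58 kept it with each array left out, and 20 lost it without at least 1 array. Over all alternatives 40 of the 78 lost it at least once while keeping their direction. Losses with a change of sign, as for C11orf96, RGCC and HMGA2 without _x_at and _s_at probe sets, were not counted in the 40. Genes with no probe set left in an alternative, such as NR4A2, TNFAIP6 and MAP3K7CL in that one, were not counted for it.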

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

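The tests of the patterns below were chosen after the results were seen, except the splits of the samples and the test of leaving out single arrays.

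Past the adjusted p threshold in limma, with every probe set tested singly, were 47 of the 13522 probe sets that gave no gene result. Of these, 38 had no gene in the annotation used here and 9 had several, and 28 were higher and 19 lower with extract. They stood out because they carry a difference from control in data that the gene results leave aside, and they are not named here.

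The rise of cytokine and interferon genes covered 40 genes over both lists, with a median log2 change of 0.72. Binding of another transcript by the chosen probe set alone would leave a gene's further probe sets without a common direction. Their mean change was positive in 90.9% of the 22 genes that have any, with an exact 95% interval of 70.8% to 98.9%, which argues against it for these genes. Another transcript bound by several probe sets of a gene would raise them together, so this stays open, as does the case of genes with no further probe set. A single aberrant array is argued against in part, since at least 27 of the 40 genes stayed called with each array left out. The 40 were chosen as called on these same arrays, with separated groups, which leans this test towards that result. RNA of leukocytes stays open, since 16 of 17 leukocyte markers (median change -0.0395, 95% order-statistic interval -0.137 to 0.0578) were no brighter in control than the median gene, and the brightest, CD14 at an intensity of 63.7, chosen after its value was seen, was at 0.41 with limma adjusted p = 0.0591, passing over the list alone and without control replicate 3. The extract itself may be behind the rise, but so may a contaminant of it such as endotoxin, which was not tested, so these stay open as hypotheses.

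With 6 arrays there are 10 splits into 3 and 3, which is too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave as many changed genes (620, highest other 0), as many genes changed at least 1.5-fold (193, highest other 0) and as many called lists (15, highest other 8).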

How the results depend on the processing

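The alternative without replicate 3 of both groups was added after seeing the data. Changed genes numbered 254 with a replicate block, 1152 without dim genes, 1305 with a trended and robust prior, 410 without _x_at and _s_at probe sets, 126 without both replicates 3, 1023 at adjusted p under 0.1, and 275 to 351 with 1 array left out. All 620 genes kept their direction with 1 array left out, which was fixed in advance because all 620 had separated groups. The deviations of same-numbered arrays from their group means correlated at -0.059, 0.046 and -0.18, and those of differently numbered arrays at -0.12 to 0.16. This gave no sign of pairing by replicate number, but 3 arrays per group are too few to show that there was none. With the replicate block 251 of the 620 calls were kept. Genes changed at least 1.5-fold numbered 126 with the mean of probe sets and 119 without both replicates 3, and 469 at a fold of 1.3 and 36 at a fold of 2. With an estimated correlation camera called 1 list, NF-kB cytokines, and adjusted p was 0.33 for interferon and LXR genes, 0.427 for hypoxia, immediate early, autophagy and prostaglandin genes, 0.147 for glucocorticoid genes, 0.494 for proteasome, contractile and PPAR genes, 0.507 for chaperones, 0.445 for NRF2, 0.426 for cholesterol and 0.638 for smooth muscle markers. Without _x_at and _s_at probe sets adjusted p was 0.254 for immediate early, 0.0764 for PPAR, 0.177 for chaperone, 0.0868 for NRF2 and 0.0747 for prostaglandin genes. In fry it was 0.112 for contractile genes, 0.0741 for chaperones, 0.0913 for NRF2 and 0.17 for smooth muscle markers. The other 11 lists called by camera passed in fry, which does not compare a list with other genes, as did 4 lists that camera did not call. Without both replicates 3 it was 0.186 for NRF2, 0.159 for cholesterol and 0.32 for smooth muscle markers, which also had 0.0692 with array weights and 0.0605 with the mean of probe sets. Prostaglandin genes had 0.118 without dim genes and 0.0597 with quantile normalization again. Leaving out 1 array gave 0.00525 to 0.0754 for NRF2, 0.011 to 0.0507 for cholesterol, 0.00702 to 0.298 for smooth muscle markers and 0.0122 to 0.147 for prostaglandin genes, and the other 11 called lists kept their calls. Without _x_at and _s_at probe sets C11orf96 was at -0.0421, RGCC at -0.00789, HMGA2 at 0.0402 and PALLD at 0.0687, because other, dim probe sets then stand for these genes, and CDKN1A ranged from -0.0241 to 0.0101 with 1 array left out, the highest without control replicate 1. For the remaining changes the cause was not tested. No detection calls were used here, so no level was shown to lie above background.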

Other observations

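NRG1 and GDF15, growth factor genes of the ErbB ligand and TGF-beta families, rose among 19 secreted growth factor genes of fibroblasts, by 0.65 ± 0.06 and 0.62 ± 0.06 (log2 ± SE, limma), while FGF5 fell by 0.50 ± 0.06. GDF15 rests on an _x_at probe set, and its further probe sets were at 0.02 and 0.19, with no call. In all 3 of these 19 rose and 3 fell (7 and 5 when adjusted over the list alone), and camera did not call the list (adjusted p = 0.396). BAMBI, a decoy receptor that dampens TGF-beta signals, rose by 0.69 ± 0.07 and BHLHE40, a circadian repressor, by 0.68 ± 0.08, among 3 of 21 TGF-beta targets that rose and 1 that fell (6 and 3 over the list alone, camera adjusted p = 0.442). When any array but control replicate 2 was left out, 2 rose and 0 fell. Of 27 BMP and Wnt targets 4 rose and 2 fell (5 and 3 over the list alone), with camera adjusted p = 0.326, but 1 rose and 0 fell without control replicate 2, extract replicate 1 or extract replicate 2, 1 rose and 1 fell without extract replicate 3, 2 rose and 0 fell without control replicate 1, and 2 rose and 1 fell without control replicate 3. Of 29 genes of DNA replication and G1/S 1 rose and 3 fell, also over the list alone, with camera adjusted p = 0.442 and a median of 0.01 against a mean of -0.04. These were UNG, which rose, and UHRF1, RRM1 and RRM2, which fell, and each lost its call with at least 4 arrays left out in turn, with adjusted p up to 0.128. Of all 44 lists camera did not call 29, and fry called 4 of these, matrix proteases at adjusted p = 0.0185, aryl hydrocarbon receptor targets at 0.0286, both higher, conjugating enzymes and transporters at 0.0379, higher, and replication-dependent histones at 0.0469, lower. IRS2, an adaptor of the insulin receptor, rose by 0.88 ± 0.07, and EGR1, an immediate early gene, by 0.75 ± 0.10, both chosen after their values were seen, and both kept their calls with each array left out.

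The tests below were set after the results that raised them had been seen. PDK4, SST and NR4A2, picked from the 12 largest rises after these were seen, are known targets of cAMP/CREB or FOXO signalling. Among the 12, the rise of NR4A2 was larger than only that of GABRA2. The 3 picked genes raised the hypothesis that one of these pathways may lie behind the largest rises. With all 32 measured members each, cAMP/CREB targets had adjusted p = 4.65e-14 and FOXO targets adjusted p = 2.39e-06 in limma's camera, adjusted over the 3 lists tried, and both were higher, but the lists were written from genes already seen to rise. Leaving out the members noticed at first, the unadjusted camera p was 0.0194 for CREB (0.064 with an estimated correlation) and 0.208 for FOXO, but more members proved to have been seen, and without these p was 0.485 for the 11 remaining CREB targets and 0.508 for the 14 remaining FOXO targets. What remains holds no called gene by construction, which leans these tests towards no result, so both hypotheses stay open. For binding of another transcript, the further probe sets had a positive mean change in 87.5% of 8 of the 12 genes with the largest rises (exact 95% interval 47.3% to 99.7%), which leaves it open; a first count by probe set, 80% of 15, was replaced because probe sets of 1 gene are not independent, as was 85.7% of 28 for the cytokine and interferon genes.

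CCND1, E2F7, HMGA2 and HBEGF fell on their brightest probe sets, and fewer cycling cells would lower the mitosis list with them. Its median log2 change was 0.0322, with a 95% order-statistic interval of -0.0156 to 0.0853, which lies wholly above the fall of CCND1, as does that of its 17 members above the median gene in control, at -0.0125 to 0.181. The list thus showed no fall as large as that of CCND1, but fewer cycling cells need not lower it that far. Both intervals also hold small falls, so a small drop in cycling cells stays open. A candidate explanation is lower output of YAP/TEAD, the transcription factors of the Hippo pathway. The 15 YAP/TEAD targets whose values had not been seen had a median log2 change of -0.19, and their unadjusted camera p was 4.88e-05 (0.000146 adjusted over the 3 lists). With an estimated correlation the unadjusted camera p was 0.0322, against 0.505 for the CREB and 0.521 for the FOXO targets not seen before. After adjustment over the 3 lists that value would not stay under 0.05. Lower YAP/TEAD output is a hypothesis found and tested on the same arrays, and of all 21 measured targets 1 rose and 2 fell.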
